A study of Mus musculus with 8 samples.

How the data were processed

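Ribosome-bound RNA of astrocytes from the brains of mice with the RiboTag allele was sequenced in 8 libraries, 4 labelled GL261 glioma and 4 labelled sham. Per the labels' protocols, polyribosomes were immunoprecipitated, ribosomal RNA was depleted, and libraries were made with NEBNext kits and sequenced on an Illumina NextSeq. The authors deposited 1 table of estimated counts per gene, not scaled to a common total. Per the submitters' processing notes, kallisto, RSEM and the mm10 build were used, with no versions and no statement of which step each served. The gene annotation, the strand setting and any filters were not given in the sources used here. Of the deposited values, between 40.4% and 52.4% per library were not whole, so the estimated counts were rounded before any count test. The table held 20778 genes and 0 rows without a gene name, and 2941 genes were at 0 in every library.

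Columns were assigned to samples by the S-number that closes each sample's description, which was the only label to match the column names. The 8 columns were all used. Column order and values were not used to assign a condition. The labels do not say whether libraries came from separate mice, so p-values measure the spread between these libraries. No pair of libraries agreed within sampling noise: over genes with at least 20 counts in the pair, chi-square per degree of freedom was between 5.15 and 148 for the 28 pairs. No library was thus a second copy of another, and all 8 were kept. This check cannot tell whether libraries share a mouse.

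Library totals were between 3256029 and 9109152 estimated counts, and between 15078 and 16483 genes were above 0 per library. The 10 most abundant genes took between 9.49% and 18.1% of the counts. TMM factors were between 0.824 and 1.19. CPM are estimated counts scaled to a common library total with TMM factors, and log2 CPM were computed with a prior count of 2.

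Genes were filtered with filterByExpr by labelled group, which left 13083, and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 48.3%. Standard errors were derived from the log2 fold change and the F statistic. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, over lists with at least 3 tested members, and beside it with an estimated correlation and with fry. Each list's spread over the 8 libraries was set against 10000 random lists of the same size matched on mean expression.

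The 39 lists held 583 genes, of which 562 were in the table, and covered astrocyte states, cholesterol, inflammation, metabolism, stress, other cell types and proliferation. The lists, tests and the rule for named genes were fixed before the data were examined. The rule named the 10 genes with the largest change in each direction among those that passed, with an average of at least 3 log2 CPM, non-overlapping groups and an established symbol, of which there were 0. It also named 14 fixed genes, among them Gfap, Rpl22, Aqp4, Slc1a2, Ccl2, Csf1, Il33, Abca1, Abcg1, Apoe, Sqle, Cd274 and Mki67, and, in each list, up to 3 members that passed in the leading direction and 1 in the other, or the 2 most abundant members where none passed. The lists for B cells, neutrophils and red blood cells had 1, 1 and 2 tested members and were not tested, and the list for the mitochondrial genome matched 0 of its 13 members, since the table names these genes as COX1 or ND4.

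The fits were tested on simulated data for libraries labelled glioma against sham, with 13083 genes and 100 genes changed at each size. With no set structure, 55% of genes changed by a log2 of 1 and 86% of those changed by 2 were recovered, with 8 false calls. With the 2 sets of columns built in, the fit with group alone recovered 0% and 38%, with 0 false calls, and the fit with group and set 52% and 92%, with 10 false calls. Each gene was drawn with the same dispersion in all 8 libraries, so these rates may not hold where the spread differs between libraries. In a simulation of 35 lists with no set structure and genes drawn independently, the list that was shifted by a log2 of 1 was called and 0 others were. It says nothing about false calls where the genes of a list vary together.

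Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, other scalings (DESeq2 size factors, upper quartile, library totals only), no filter and a filter of 1 CPM in 4 libraries, an adjusted p under 0.01, glmTreat against a log2 fold change of 1, the replicate number as a block, and each library left out in turn. Fits with the set of columns as a term, or within columns S1 to S4 or S5 to S8, were added after the data were seen. The labelled split was compared with all 35 splits of the 8 libraries into 4 and 4. Gene coordinates and transcript lengths came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by symbol, with 99.2% of the table's symbols found. Figures were drawn with matplotlib 3.10.9.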

Results

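The series profiled RNA bound to ribosomes of mouse astrocytes. The mice carried a Cre recombinase under the promoter of Gfap, an intermediate filament gene of astrocytes, and a Cre-dependent haemagglutinin tag on Rpl22, a protein of the large ribosomal subunit. In the RiboTag method, tagged polyribosomes are pulled out of brain lysate with an antibody, together with the RNA they are translating. Mice had received GL261 cells, a mouse glioma line, into the brain, or an injection of PBS as a sham. There were 8 libraries, 4 labelled GL261 glioma and 4 labelled sham, and the question was how astrocyte RNA differed between the tumour-bearing and the sham brain.

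The deposited table gave estimated counts for 20778 genes, in columns named S1 to S8. The totals were 3256029, 3621005, 4905638 and 3740099 counts in S1 to S4 and 7013034, 9109152, 3340414 and 3531009 in S5 to S8. The labels named columns S6, S7, S2 and S1 for glioma libraries 1 to 4, and columns S3, S4, S8 and S5 for sham libraries 1 to 4, and the groups below follow those labels. The values cut across them. Libraries in columns S1 to S4 resembled each other, as did those in columns S5 to S8, and each of these sets held 2 libraries labelled glioma and 2 labelled sham. Which column belonged to which mouse could not be settled from the labels and values, so every direction and count below holds only if the columns are those the labels name. Another numbering of the columns would change the counts as well as the directions: the split of S1 to S4 against S5 to S8 gave 7547 genes where the labelled split gave 0.

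Between the labelled groups, edgeR found no gene that differed beyond the spread between replicates. Gfap was at 572 ± 87.0 CPM, counts scaled to a common library total (SD, n = 4), in the libraries labelled glioma and 809 ± 369 (SD, n = 4) in those labelled sham. The glutamate transporter gene Slc1a2 was at 6104 ± 4797 and 5614 ± 3125 CPM, and the proliferation marker Mki67 at 172 ± 191 and 127 ± 135 CPM (SD, n = 4 in each group). Of 13083 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower in the libraries labelled glioma at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.9998. In simulations with the 2 sets of columns built in, this fit recovered 0% of genes changed by a log2 of 1 and 38% of those changed by 2. At an unadjusted p under 0.05 there were 36 genes, 16 higher and 20 lower, where chance alone would give about 654. The 4 libraries of a group lay entirely on one side of the other 4 for 72 genes, or 0.550%, where chance gives 2.86%. Both chance values are for interchangeable libraries. Here each labelled group held 2 libraries of each set of columns, which widened the spread within groups. Among other splits of this kind, S1, S4, S6 and S8 against the rest gave the fewest genes at that unadjusted p, 12. The most, 229, came with S1, S3, S5 and S8 as one group. The 36 lay within this range. Neither shortfall can thus be read as groups more alike than chance. DESeq2 called 1 gene higher and 0 lower, with 90 genes at an unadjusted p under 0.05, and limma voom with sample weights called 0, with 1463 at an unadjusted p under 0.05. The weights of the libraries labelled sham were 3.09 and 3.21 for S5 and S8 and 0.433 and 0.349 for S3 and S4. In the libraries labelled glioma they were between 0.624 and 1.54. This unbalances the sets between the groups, so the 1463 cannot be read as a difference between the labels. The DESeq2 gene, Lgi2, named here after its values were seen, had 31, 56, 20 and 7 counts in S1, S2, S6 and S7, labelled glioma, and 0 in all 4 libraries labelled sham.

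The 35 tested gene lists gave 1 call. The neuron list was lower in the libraries labelled glioma, with 16 of its 17 tested members at a negative log2 fold change and a median of -0.31. Its mean level was 7.74 ± 0.54 log2 CPM against 8.05 ± 0.61 in the libraries labelled sham (SD, n = 4 in each group), and the adjusted p of limma's camera with a preset correlation was 0.0185. With an estimated correlation its adjusted p was 0.999 (p = 0.345). The call was also lost without glioma 3 (adjusted p = 0.349), glioma 4 (0.434), sham 3 (0.336) or sham 4 (0.528). Among its most abundant members, Camk2a, a calcium and calmodulin-dependent kinase subunit of excitatory neurons, was at 2085 ± 1177 and 3529 ± 2309 CPM, with a log2 fold change of -0.76 ± 0.63 (SE, edgeR adjusted p = 0.9998). The synaptic vesicle fusion gene Snap25 was at 623 ± 129 and 605 ± 92.7 CPM (SD, n = 4 in each group). None of the list's members passed over all genes, and 0 passed adjusted over the list alone. The astrocyte identity list was at 8.03 and 8.24 log2 CPM, near the level of the neuron list. Which cells the RNA of the neuron genes came from was not tested.

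**Figure D1:**
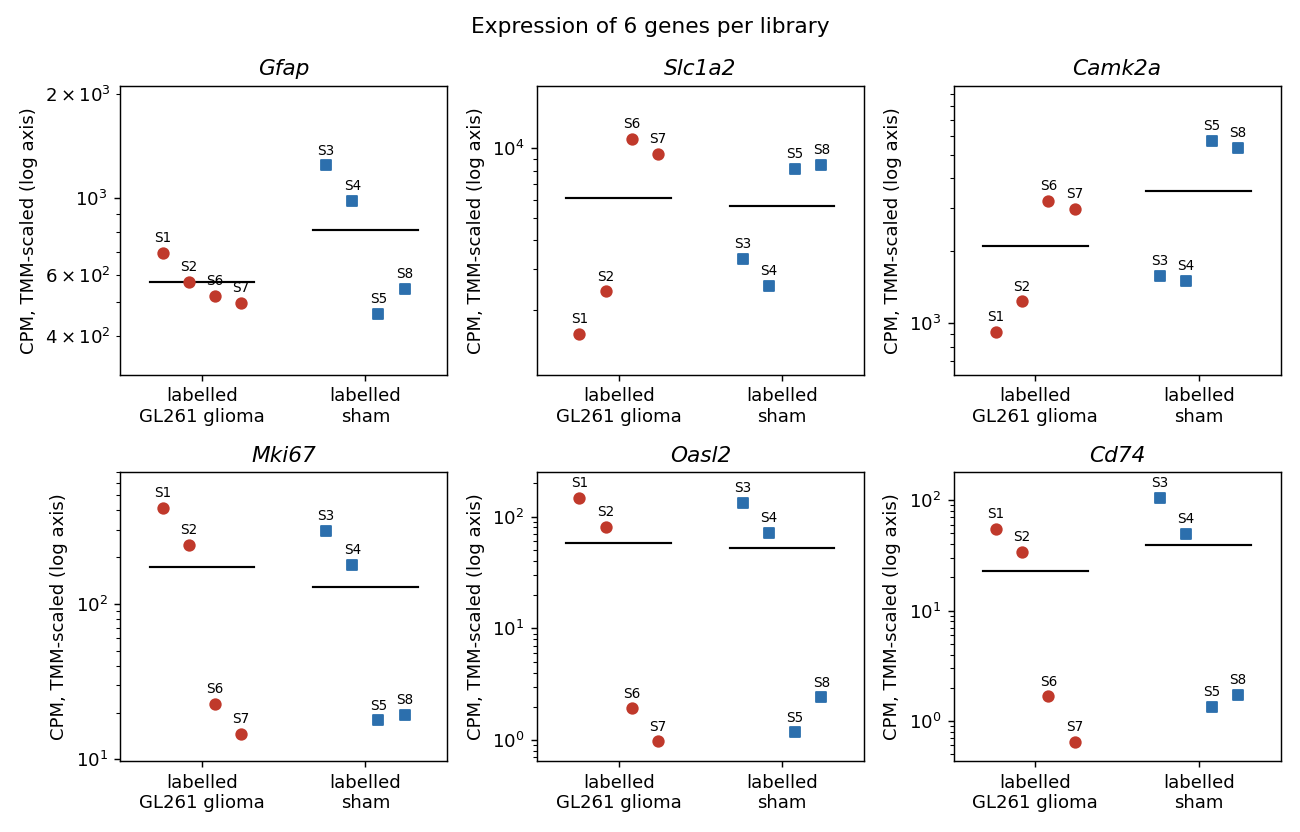
Each point is a library, marked with its column name, with CPM after TMM scaling on a log axis for 6 genes, by labelled group (red circles glioma, blue squares sham, n = 4 each); black lines are group means. For Mki67, Oasl2 and Cd74 each labelled group holds 2 high and 2 low libraries, and Mki67 ranged from 14.6 CPM in S7 to 412 CPM in S1.

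The spread between replicates was wide because each labelled group held libraries of both sets. Mki67 was at 412, 240, 296 and 177 CPM in S1, S2, S3 and S4, of which S1 and S2 were labelled glioma and S3 and S4 sham. It was at 17.8, 22.8, 14.6 and 19.3 CPM in S5, S6, S7 and S8, of which S6 and S7 were labelled glioma. Pearson's r across genes was between 0.754 and 0.969 for pairs of libraries with the same label and between 0.729 and 0.977 for pairs with different labels; genes are not independent replicates. Within columns S1 to S4 it was between 0.900 and 0.951, within S5 to S8 between 0.947 and 0.977, and between the sets between 0.729 and 0.843.

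**Figure D2:**
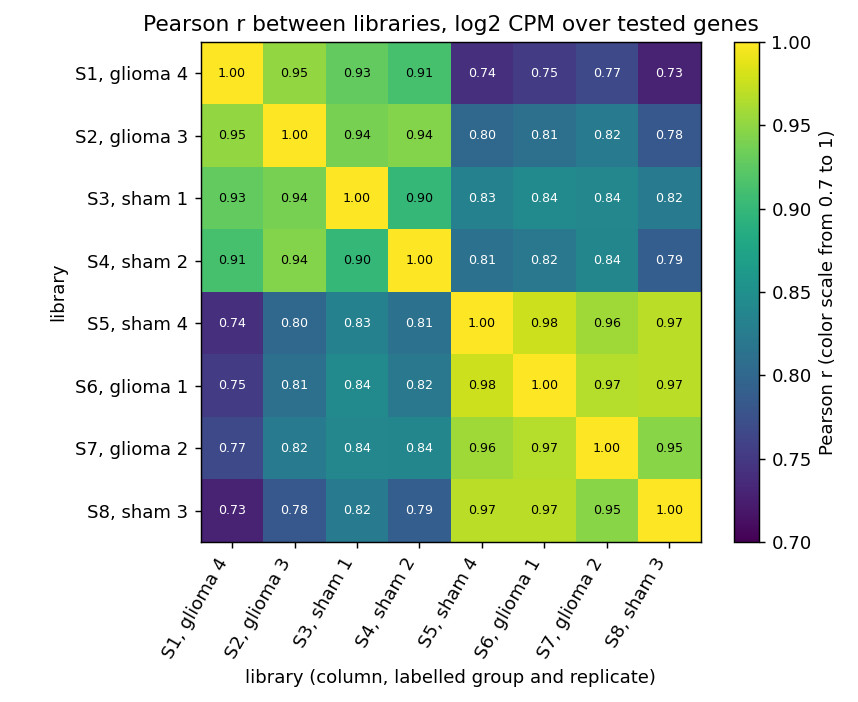
Pearson's r of log2 CPM across tested genes for each pair of the 8 libraries, which are listed on both axes by column, labelled group and replicate; the color scale runs from 0.7 to 1. Pairs within columns S1 to S4 lie between 0.900 and 0.951 and pairs across the sets between 0.729 and 0.843, whichever group the labels give.

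Astrocyte genes such as Slc1a2 and Glul were abundant in all 8 libraries, and whether their list was called depended on how the 2 sets of columns were handled and on single libraries. In the astrocyte identity list, 9 of 24 members had a positive and 15 a negative log2 fold change (camera adjusted p = 0.443), with levels of 8.03 ± 1.26 and 8.24 ± 0.91 log2 CPM in the libraries labelled glioma and sham (SD, n = 4 in each group). With the set as a term the list was lower in the libraries labelled glioma (adjusted p = 0.0276), and in S1 to S4 alone as well (4.10e-09), calls that were lost with an estimated correlation (adjusted p = 0.986 and 0.968). In S5 to S8 alone the astrocyte identity list took the opposite direction without passing (adjusted p = 0.194). The list was also called lower without sham 2 (adjusted p = 0.0159), glioma 1 (0.00243) or glioma 2 (0.000859). These calls too were lost with an estimated correlation (camera adjusted p = 0.938, 0.900 and 0.936). The water channel gene Aqp4 was at 237 ± 222 and 230.1 ± 150 CPM, and Glul, which encodes glutamine synthetase, at 2984 ± 1902 and 2844 ± 1546 CPM (SD, n = 4 in each group). Slc1a2 was at 1577, 2407, 3316 and 2534 CPM in S1 to S4 and at 8126, 10945, 9487 and 8480 CPM in S5 to S8. Of 10 pan-reactive members, 3 were positive and 7 negative (adjusted p = 0.997), and Vim, another intermediate filament gene, was at 144 ± 147 and 161 ± 178 CPM (SD, n = 4 in each group). The A1 list had 6 of 10 members positive (adjusted p = 0.819) and the A2 list 5 of 9 (adjusted p = 0.976). The tagged gene Rpl22 was at 48.8 ± 23.2 and 34.6 ± 15.9 CPM (SD, n = 4 in each group), with a log2 fold change of 0.50 ± 0.41 (SE, edgeR adjusted p = 0.9998). Among factors that act on synapses, 6 of 12 members were positive (camera adjusted p = 0.565), with Sparcl1 at 1845 ± 1547 and 1837 ± 1306 CPM (SD, n = 4 in each group).

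Neither cholesterol list passed, and Abca1 and Sqle differed little between the 8 libraries. Abca1, a cholesterol exporter, was at 101 ± 5.66 CPM in the libraries labelled glioma and 98.6 ± 12.9 CPM in those labelled sham (SD, n = 4 in each group), and its log2 fold change was 0.03 ± 0.16 (SE, edgeR adjusted p = 0.9998). Sqle, which encodes squalene epoxidase, an enzyme of cholesterol synthesis, was at 53.4 ± 4.76 and 50.6 ± 3.82 CPM (SD, n = 4 in each group). Abcg1, a further exporter, was at 50.9 ± 11.9 and 64.8 ± 23.5 CPM, and the lipoprotein gene Apoe, whose libraries ranged from 629 CPM in S4 to 3185 CPM in S8, at 1849 ± 1257 and 1843 ± 1173 CPM (SD, n = 4 in each group). Of the synthesis list, 11 of 21 members were positive (camera adjusted p = 0.976), with Hmgcs1 at 221 ± 73.3 and 237 ± 66.9 CPM and Srebf2 at 174 ± 36.6 and 212 ± 59.9 CPM. Of the transport list, 5 of 17 were positive (adjusted p = 0.443), with Lrp1 at 632 ± 188 and 710.0 ± 199 CPM.

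Interferon and antigen presentation genes varied widely between libraries of one label. Of the type I interferon list, 17 of 21 members were positive (camera adjusted p = 0.819), but its level was 3.47 ± 2.10 log2 CPM in the libraries labelled glioma and 3.38 ± 2.13 in those labelled sham (SD, n = 4 in each group). Oasl2, an interferon-induced gene, was at 147, 81.1, 133 and 71.6 CPM in S1 to S4 and at 1.18, 1.92, 0.975 and 2.41 CPM in S5 to S8. Stat2 was at 41.7 ± 33.9 and 49.7 ± 32.9 CPM (SD, n = 4 in each group). Of the MHC class I list, 8 of 17 members were positive (adjusted p = 0.819), with H2-D1 at 80.5 ± 82.0 and 94.9 ± 104 CPM and B2m at 62.7 ± 20.8 and 78.6 ± 52.7 CPM. All 7 tested MHC class II members were negative (adjusted p = 0.976), with Cd74, the invariant chain, at 22.8 ± 26.5 and 39.5 ± 49.4 CPM and the protease gene Ctss at 30.1 ± 22.97 and 33.2 ± 31.3 CPM. Cd274, which encodes the checkpoint ligand PD-L1, was at 35.1 ± 37.4 and 23.7 ± 24.2 CPM, and Vsir at 28.9 ± 9.51 and 28.4 ± 8.56 CPM (SD, n = 4 in each group), in a checkpoint ligand list with 4 of 9 members positive (adjusted p = 0.443). Gbp2, an interferon-induced GTPase gene of the A1 list, was at 217, 114, 179 and 102 CPM in S1 to S4 and at 0.839, 1.15, 2.28 and 1.72 CPM in S5 to S8.

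Lists of cytokine signalling gave no call between the labelled groups. The chemokine and cytokine list had 6 of 15 members positive (camera adjusted p = 0.989). Csf1, a growth factor of macrophages, was at 27.2 ± 9.57 and 25.4 ± 11.9 CPM, and the alarmin gene Il33 at 41.6 ± 29.9 and 44.7 ± 23.7 CPM (SD, n = 4 in each group). Cx3cl1 was at 177 ± 88.0 and 205 ± 73.6 CPM and Cxcl14 at 122 ± 92.1 and 128 ± 81.4 CPM (SD, n = 4 in each group). The chemokine gene Ccl2 was too low to be tested, with 9, 7, 20 and 6 counts in S1 to S4 and 0, 1, 0 and 0 in S5 to S8. The complement list had 5 of 11 members positive (adjusted p = 0.443), with C4b at 114 ± 80.0 and 129 ± 112 CPM. Of the NF-kappaB targets, 8 of 13 were positive (adjusted p = 0.976), with Sod2 at 169 ± 21.02 and 175 ± 13.6 CPM and Vcam1 at 40.6 ± 21.8 and 38.9 ± 12.8 CPM. Of the STAT3 list, 3 of 10 were positive (adjusted p = 0.989), with Il6st at 126 ± 20.8 and 128 ± 10.7 CPM and Lifr at 92.5 ± 38.1 and 97.3 ± 20.8 CPM.

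Metabolic, stress and matrix lists also gave no call. Glycolysis had 3 of 18 members positive (camera adjusted p = 0.252), with Gapdh at 551 ± 458 and 680 ± 525 CPM and Pkm at 582 ± 87.3 and 739 ± 265 CPM (SD, n = 4 in each group). Oxidative phosphorylation had 9 of 27 positive (adjusted p = 0.865), with Atp5b at 440 ± 143 and 501 ± 215 CPM and Sdha at 244 ± 113 and 290 ± 142 CPM. Hypoxia genes had 8 of 13 positive (adjusted p = 0.989), with Vegfa, the vascular growth factor, at 79.1 ± 10.5 and 80.1 ± 15.3 CPM and Egln1 at 87.3 ± 13.4 and 104 ± 22.997 CPM. The unfolded protein response had 9 of 14 positive (adjusted p = 0.976), with the chaperone genes Hsp90b1 at 412 ± 234 and 331 ± 181 CPM and Hspa5 at 241 ± 57.2 and 220 ± 93.3 CPM. Immediate early genes had 5 of 13 positive (adjusted p = 0.819), with Arc at 158 ± 121 and 220 ± 164 CPM and Egr1 at 94.0 ± 15.1 and 88.3 ± 16.1 CPM. Extracellular matrix had 11 of 18 positive (adjusted p = 0.446), with Sparc at 420 ± 271 and 433 ± 234 CPM and Ncan at 320 ± 163 and 322 ± 118 CPM. Ribosomal proteins had 16 of 31 positive (adjusted p = 0.819), with Rpl4 at 236 ± 38.4 and 240 ± 56.9 CPM and Rpl3 at 191 ± 16.6 and 195 ± 58.3 CPM.

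Markers of dividing cells and of other cell types were present in the immunoprecipitates. The proliferation list had 17 of 21 members positive (camera adjusted p = 0.443), at 3.48 ± 1.89 and 3.22 ± 1.79 log2 CPM in the libraries labelled glioma and sham (SD, n = 4 in each group). Top2a, a topoisomerase gene of dividing cells, was at 455, 275, 381 and 175 CPM in S1 to S4 and at 7.72, 9.36, 8.45 and 7.92 CPM in S5 to S8. Neural progenitor genes had 8 of 12 positive (adjusted p = 0.819), with Sox2 at 98.3 ± 9.80 and 94.0 ± 25.3 CPM and Sox11 at 81.5 ± 2.86 and 93.2 ± 11.2 CPM. Oligodendrocyte genes had 2 of 11 positive (adjusted p = 0.443), with the myelin gene Mbp at 603 ± 61.8 and 644 ± 48.5 CPM (SD, n = 4 in each group). Oligodendrocyte precursor genes had 2 of 8 positive (adjusted p = 0.967), with Olig1 at 125 ± 12.8 and 141 ± 46.6 CPM and Olig2 at 46.0 ± 24.9 and 49.6 ± 29.4 CPM.

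Among immune cell markers, the microglia list had 9 of 11 members positive and an adjusted p of 0.118. The pan-myeloid list had 1 of 13 positive (adjusted p = 0.819), with Csf1r at 39.8 ± 14.1 and 43.9 ± 19.5 CPM and Ptprc at 19.7 ± 13.2 and 21.03 ± 21.5 CPM. The blood-derived macrophage list had 8 of 9 positive (adjusted p = 0.146), with Itga4 at 78.1 ± 26.5 and 77.5 ± 56.7 CPM and Vcan at 64.0 ± 9.96 and 47.5 ± 13.3 CPM. That list was called higher without sham 1 (adjusted p = 0.0298), sham 2 (0.0164) or glioma 1 (0.0178). With an estimated correlation these calls were lost (camera adjusted p = 0.701, 0.938 and 0.900). The T and NK cell list had 3 of 4 positive (adjusted p = 0.819), with Cd3d at 11.1 ± 10.04 and 8.88 ± 11.5 CPM and Cd4 at 5.82 ± 2.47 and 4.93 ± 3.25 CPM. Endothelial genes had 7 of 11 positive (adjusted p = 0.443), with Flt1 at 24.4 ± 10.4 and 24.5 ± 8.24 CPM and Pecam1 at 17.6 ± 8.99 and 17.0 ± 7.15 CPM. Pericyte and smooth muscle genes had 2 of 6 positive (adjusted p = 0.284), with Mcam at 35.7 ± 36.6 and 33.4 ± 39.7 CPM and Pdgfrb at 14.9 ± 7.94 and 17.7 ± 6.32 CPM. Fibroblast and meningeal genes had 5 of 7 positive (adjusted p = 0.989), with Col3a1 at 82.1 ± 99.2 and 60.8 ± 101 CPM and Pdgfra at 39.3 ± 6.69 and 38.2 ± 9.94 CPM. Ependymal and choroid plexus genes had 3 of 6 positive (adjusted p = 0.976), with Ttr at 65.6 ± 32.4 and 59.9 ± 30.6 CPM and Enpp2 at 115 ± 32.9 and 125 ± 12.2 CPM.

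Of the 76 named genes tested, 35 had a positive and 41 a negative log2 fold change, from -0.80 for Cd74 to 0.70 for Cd109, a surface glycoprotein gene at 20.8 ± 21.03 and 12.7 ± 13.4 CPM (SD, n = 4 in each group), and 67 were smaller in size than their standard error. S100a10, which like Cd109 belongs to the A2 list, was at 8.76 ± 1.89 and 10.2 ± 2.56 CPM (SD, n = 4 in each group). For 9 lists the median, the mean and the direction of camera differed in sign: the pan-reactive, A1, cholesterol synthesis, chemokine, MHC class I, checkpoint ligand, complement, STAT3 and fibroblast lists, whose medians were at most 0.14 from 0. No member of any tested list passed over all genes or adjusted over the list alone, and fry called 0 lists.

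Leaving out 1 library gave list calls in the libraries labelled glioma that the 8 libraries together did not, all with the preset correlation. With an estimated correlation the 8 omissions gave 0 list calls, with a smallest adjusted p = 0.701. Without sham 1, the type I interferon (adjusted p = 0.0230), MHC class I (0.0216), checkpoint ligand (0.0406), complement (0.0335), proliferation (0.00992), microglia (0.0381) and ribosomal protein (0.0116) lists were higher. Without sham 2, glycolysis (adjusted p = 0.00727) and oxidative phosphorylation (0.0159) were lower, and without sham 4 the pan-myeloid list (0.0110) was lower. Proliferation was also higher without glioma 1 (adjusted p = 0.0269) or glioma 2 (0.00948), and glycolysis and synapse-modifying factors were lower without glioma 1 (0.0392 each). Each omission leaves the 2 sets of columns in unequal numbers in the labelled groups.

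Within the sets of columns, the labelled comparison gave different counts, in fits added after the data were seen. In S5 to S8, 26 genes were higher and 224 lower in S6 and S7, labelled glioma, than in S5 and S8, labelled sham (edgeR, n = 2 in each group). The lower genes included 5 of the 17 neuron list members, Syn1, Camk2a, Nefh, Gad2 and Eno2. Camk2a was at 3214 and 2975 CPM in S6 and S7 and at 5700 and 5349 CPM in S5 and S8, a log2 fold change of -0.82 ± 0.16 (SE, edgeR adjusted p = 0.0259). In S1 to S4, 1 gene was higher and 0 were lower in S1 and S2 than in S3 and S4, and 0 neuron list members passed, although 14 of 17 were negative. That gene was Akap13, with 48.6 and 53.0 CPM in S1 and S2 and listed at 0 in S3 and S4. Camk2a was at 919 and 1232 CPM in S1 and S2 and at 1571 and 1495 CPM in S3 and S4, a log2 fold change of -0.49 ± 0.28 (SE, edgeR adjusted p = 0.9997). Whether the changes differed between the sets was not tested. With the set as a term in a fit to all 8 libraries, 0 genes passed, 1144 had an unadjusted p under 0.05, and the neuron (adjusted p = 4.12e-06) and astrocyte identity (0.0276) lists were lower and the proliferation list (0.0402) higher in the libraries labelled glioma. With an estimated correlation these calls were lost, at adjusted p = 0.841 for the neuron list, 0.986 for astrocyte identity and 0.964 for proliferation.

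On the mouse genome build GRCm38, Gfap lies on chromosome 11 from 102887336 to 102900912, Slc1a2 on chromosome 2 from 102658659 to 102790784, Mki67 on chromosome 7 from 135689784 to 135716361 and Rpl22 on chromosome 4 from 152325742 to 152334071. Camk2a and Cd74 both lie on chromosome 18, from 60925618 to 60988152 and from 60803848 to 60812652, and Oasl2 lies on chromosome 5 from 114896936 to 114912234. Counts were per gene, so they did not separate exons, introns or UTRs.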

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

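Among 226 groups of 4 libraries examined for a value far from the rest (named genes, list levels, totals and genes above 0), 1 stood apart. About 11 would do so by chance if the values of each group were normally distributed. Each labelled group holds libraries of both sets, which for many genes and lists puts the largest gap in the middle. The low count is thus no sign that outliers are rare. The library labelled glioma 1, in column S6, had a total of 9109152 estimated counts, and the others labelled glioma had between 3256029 and 3621005. The gap was 0.938 of the group's range, above Dixon's critical value for 4 libraries. Its TMM factor was 0.858, and all comparisons were scaled for library size.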

How the results depend on the processing

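The fits by set of columns were chosen after seeing the data; the other alternatives were planned. The counts of higher and lower genes stayed at 0 with DESeq2 size factors, upper quartile, library totals only, no filter, 1 CPM in 4 libraries, an adjusted p under 0.01, glmTreat, voom and the set as a term. No scaling moved the median log2 fold change of all genes by more than 0.1. DESeq2 gave 1 higher gene, Lgi2. Leaving out each library in turn gave 0 higher genes and between 0 and 1 lower genes, the latter without glioma 3, AI593442, listed at 0 in S1, S6 and S7 and at 170 counts in S2, the library left out. Deviations of same-numbered libraries correlated across genes between -0.76 and -0.57, but each such pair crosses the 2 sets of columns, so whether the replicate numbers pair the samples could not be told from this. With the replicate block the counts were 0 higher and 0 lower genes, with 10 at an unadjusted p under 0.05, and 1 list. Columns S5 to S8 alone gave 26 higher and 224 lower genes and 2 lists (neuron and microglia), S1 to S4 alone 1 higher gene and 4 lists (astrocyte identity, synapse-modifying, proliferation and neuron), and the set as a term 3 lists. These fits remove the difference between the sets from the spread, and the smaller ones use 4 libraries. The number of lists called was 1 with DESeq2 size factors, library totals only and without a filter, 0 with an estimated correlation (also with the set as a term, within S1 to S4 or S5 to S8, and without each library in turn, all added after seeing the data) or fry, and with the preset correlation between 0 and 9 when a library was left out: 9 without sham 1, 6 without glioma 1, 5 without sham 2, 3 without glioma 2, 1 without sham 4 and 0 without glioma 3, glioma 4 or sham 3. Without sham 4 the list called was the pan-myeloid list, not the neuron list. Over 28 alternatives the neuron list was lower in all and passed in 11, with adjusted p between 4.12e-06 and 0.9997. Leaving out a library unbalances the sets between the groups; otherwise the cause was not tested. Of 76 named genes, 60 changed sign under some alternative while not passing in either fit, so their directions are not established and these are not counted as reversals; 1 passed in any fit, Camk2a in S5 to S8. In simulations at these depths with the set structure, the fit with group alone recovered 0% of changes of log2 1 and 38% of log2 2. Its counts of 0 thus exclude no change of log2 1. The fit with the set as a term recovered 52% and 92%. The simulations gave a gene the same dispersion in all libraries, whereas voom weights ran from 0.349 in S4 to 3.21 in S8. Recovery in the data may thus be lower, and the 0 genes of that fit do not exclude changes of log2 2.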

Other observations

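The tests of column numbering, of RNA of other cells, of all genes of the actin list and of other splits were chosen after the result was seen. Without regard to labels, the genes that varied most over the 8 libraries (the 30 with the largest SD of log2 CPM among 10215 genes, a choice made after the values were seen) included Col2a1, Apobec3 and Gpnmb. Col2a1, a fibrillar collagen gene, was at 195, 133, 181 and 33.9 CPM in S1 to S4 and at 2.01, 1.15, 0.325 and 1.38 CPM in S5 to S8. Apobec3, a cytidine deaminase gene that restricts retroviruses, was at 1033, 750.1, 1023 and 469 CPM in S1 to S4 and between 13.1 and 16.2 CPM in S5 to S8. Gpnmb, a glycoprotein gene of phagocytes and melanocytes, was at 155, 132, 151 and 56.4 CPM in S1 to S4 and at 1.34, 2.95, 3.25 and 2.76 CPM in S5 to S8.

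Of the 35 tested lists, 21 varied over the 8 libraries at or above percentile 95 of 10000 matched random lists, and 18 at or above percentile 99. The type I interferon list ranged over 4.17 log2 CPM, MHC class II over 4.27, proliferation over 3.66, pan-reactive astrocyte over 3.21 and astrocyte identity over 2.40. Of these, astrocyte identity was lower and the others higher in every library of S1 to S4 than in any of S5 to S8. Proliferation was at 5.30 and 4.92 log2 CPM in S1 and S2, labelled glioma, and at 5.10 and 4.41 in S3 and S4, labelled sham. In S5 to S8 it was between 1.64 and 1.85. Oligodendrocyte genes were at percentile 53.7, microglia at 42.8, neural progenitor at 34.3, hypoxia at 31.3 and endothelial at 31.2.

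The libraries fell into 2 sets, columns S1 to S4 and S5 to S8, that each held 2 libraries of each label, so the labelled condition cannot account for the split as the columns are labelled. After all libraries were thinned to 3255968 counts, the lowest correlation within a set still exceeded the highest between sets by 0.0569, which argues against library depth. Added RNA of other cells over an unchanged mixture would dilute astrocyte and oligodendrocyte genes alike, but the difference between these lists was 1.10, 1.26, 1.64 and 1.24 log2 in S1 to S4 and 2.76, 3.01, 2.98 and 3.20 in S5 to S8, a gap of 1.12. This speaks only to that case, since a mixture in which the astrocyte share changed could give the same gap. That the S-numbers of the columns are not those of the labels stays open and may account for the split. The labelled change correlated between the sets across genes at r = 0.127, below a bound of 0.2 chosen after the result was seen. Of the 8 other combinations of divisions, 3 gave a larger size, up to 0.183. With 2 libraries against 2 in each set, right labels could give so low an r too, so it does not decide the numbering. The series lists the glioma samples before the sham samples. Columns numbered in that order would make S1 to S4 glioma and S5 to S8 sham, the split seen here. Whether they were so numbered could not be checked. On the side of the labels, the labelled division of S5 to S8 into pairs gave 250 genes and the others 1 and 2. A set has so few such divisions that the labelled one can come first by luck, and this cannot decide the numbering. In S1 to S4 the labelled division gave 1 gene, with 302 at an unadjusted p under 0.05, and the others gave 0 and 1, with 1408 and 205. An unrecorded batch with right labels thus stays open too, as does a biological difference between the sets that the labels do not record.

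The labelled split gave 0 genes, a count that all 35 splits of the 8 libraries into 4 and 4 reach by construction, so the splits say nothing about chance. The highest of the other splits, S1 to S4 against S5 to S8, gave 7547 genes, or 57.7% of those tested, and the remaining 33 gave 0, which points to a structure of the samples that crosses the labels.

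Genes of the actin cytoskeleton were abundant in all 8 libraries. Sptan1, a spectrin gene on chromosome 2 from 29965560 to 30031451, took between 1.66% and 6.95% of the counts, and 36 actin-binding, spectrin and myosin genes, listed after the abundant genes were seen, took 7.46%, 9.69%, 11.96% and 8.65% in S1 to S4 and 17.4%, 20.3%, 20.1% and 20.96% in S5 to S8. Transcript length may account for part of it. Among tested genes with a known length, their share of summed CPM was 7.60% in S1 and 21.3% in S8, and per kilobase it was 2.54% and 10.9%. The genes stayed abundant per kilobase: their share was at least 2.54% in every library, where they make up 0.276% of the genes. The 10 most abundant had a median percentile of 99.9 per kilobase. Both measures are of genes picked for their abundance, which favours high values per kilobase too. Length was the median over a gene's annotated transcripts, not that of the transcripts expressed here. How far length accounts for the abundance was thus not settled. No biological explanation was tested.

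In 47 genes, an estimated count of 0 in at least 1 library of a set stood beside at least 100 counts in another library of that set, among them Ralgapa1 with 0, 21, 168 and 0 counts in S1 to S4 and Ube3a with 387, 198, 407 and 0. Ambiguous reads assigned to one gene or another by the estimation, differently in different libraries, may account for this: 100% of these genes had a value that was not whole, against a median of 76.6% and at most 93.6% in 1000 matched draws. No biological explanation was tested. These genes included Akap13, the 1 gene that passed within S1 to S4, and AI593442, which passed without glioma 3 and had the smallest adjusted p within S5 to S8 (edgeR, 1.04e-05), where it was 1 such gene among the 250 that passed. Counting zeros beside lower counts too, 13 of these 250 were at 0 in a library of S5 to S8, 5 of them higher and 8 lower.

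Ccdc107, on chromosome 4 from 43492900 to 43495921 on the plus strand, took 3.04% of the counts in S1 and 0.213% in S8. It overlaps Rmrp, an RNA component of a ribonuclease, annotated from 43492788 to 43493058 on the minus strand. Gm20594, a predicted gene on chromosome 6 from 79817916 to 79818364, took between 0.870% and 4.03%.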
